A study of Mus musculus with 469 samples.

How the data were processed

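The series holds 469 single-cell RNA libraries from mouse olfactory epithelium, labelled as single cells captured with the Fluidigm C1 system, made from polyadenylated RNA and prepared with Nextera XT. The number of cells per library could not be checked, and 9 reference libraries of run 1 with over 10000 genes did not resemble the other single-cell libraries. They were kept as labelled, and an alternative left them out. Samples were grouped by the labels into 3 Neurog1-eGFP sorts (uninjured, 5 days and 14 days after olfactory bulbectomy), 2 OMP-eGFP sorts (14 days after bulbectomy, and engrafted after transplantation) and an unsorted uninjured reference in 2 runs. The labels gave the strains as FVB Neurog1-eGFP, B6 OMP-eGFP and B6;129SF1/J (F1), and the age as 8 weeks in all groups. They gave no animal and no sex. Each group was therefore treated as 1 sample, and cells were not used as replicates.

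The authors deposited 2 tables with 1 column per cell. The first holds signal, that is, estimated fragments per gene which the authors scaled to nearly the same total in every cell. The second holds FPKM values computed by the authors. Per the submitters' processing notes, FastQC, STAR 2.5.2a, Cufflinks 2.2.1 and Cuffnorm were used with genome build mm9, and their roles were not stated. The annotation was not given in the sources used here. The analysis plan had assumed whole counts in the first table, but 99.9% of the nonzero values were not whole numbers, so the table was used as scaled signal.

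Of 23308 gene entries, 27 had names altered into dates (0.418% of the signal) and were left out, which left 23281. Values were expressed as CPM, the share of the cell's column sum times 10 to the power of 6. The raw depth had been removed by the scaling, but most values within a cell were whole multiples of a single smallest step, the value of 1 fragment. That step was sought for each cell with a tolerance of 0.02, and fragments per cell were recovered from it. A median of 98.5% of a library's values were whole multiples, 1 library was under 90% (28.8%) and the next lowest was at 95.1%. On simulated data the step was found in 327 of 328 cells when gene levels were widely spread (gamma shape 0.3), and in 171 of 328 when they were less so (shape 2). In both simulations none of the wrong steps reached 90% whole values, while 328 of 328 real libraries that passed the filter did.

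A library was kept when it had 1000 or more genes with a value of 1 or more and a sum of 50000 or more. The limit on the sum removed no library, since the sums had been made nearly equal, so the number of genes did the filtering. It kept 328 libraries, with 13369 to 2186034 recovered fragments. At the median depths of 501827 to 1347935 fragments per group, a CPM of 10 stood for about 5 to 13 fragments. No doublet caller was run, and the planned thinning of whole counts was replaced by thinning of recovered fragments. No replicate test, p-value or count of altered genes was computed.

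A gene was counted as found in a cell at a CPM of 10 or more, and shares were given with exact Clopper-Pearson 95% intervals. For a share of 0, the share that 0 of n cells allows was given as 3 divided by n. Differences between groups were log2 ratios of mean CPM + 1, which understate low genes. There were 7 comparisons: the uninjured Neurog1 sort over the reference, the 3 pairs of Neurog1 groups, engrafted over 14 day OMP cells, OMP over Neurog1 cells at 14 days, and OMP cells at 14 days over reference cells in clusters like mature neurons. The 29 gene lists (14 of cell type markers, 15 of processes and families) were fixed before the data were examined, and 4 of their genes (Bbs8, Dnah5, Hbb-bs, Hbb-bt) were missing from the tables. A list was summarised by the median log2 ratio of its members with a mean CPM of 5 or more in either group. Its percentile was taken among 10000 random lists of genes of like mean level, as a description and not as a test. Members listed at 0 in a group enter a median through the pseudocount of 1, so the size of such medians depends on it.

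Single genes were named from the fixed lists or by a fixed rule: the 12 highest and 12 lowest log2 ratios among genes with a mean CPM of 50 or more and a share of 30% or more in the higher group, shares whose intervals do not overlap, and a pooled ratio of the same direction. Odorant receptor, Gm, Rik and mitochondrial genes were left out of that rule. For clusters, 2000 variable genes were reduced to 20 principal components and grouped by Ward linkage into 12 clusters. A cluster was named when 3 or more markers of a type were at least 2 times higher than in the other cells and found in 30% or more of its cells, and its 10 leading genes held no more markers of another type than of its own. Odorant receptors were counted per cell at a CPM of 50 or more among 1116 Olfr entries. The Xist and Y-linked gene counts used Ddx3y, Eif2s3y, Kdm5d and Uty.

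The alternatives tried were detection at a CPM of 1 or 50 and in the FPKM table, pseudocounts of 0.1 and 10, pooled CPM, median-of-ratios size factors coded by hand, no filter on low values, list members at a CPM of 50, no cell filter, a strict cell filter (2000 genes, sum of 200000), either reference run alone, 8 or 16 Ward clusters, Leiden clustering at resolution 1 with 15 neighbours, 1000 variable genes, and receptors at a CPM of 10 or 200 or at 10 in the FPKM table. After the data were seen, 4 were added: thinning to 100000 recovered fragments, a limit of 50000 recovered fragments, leaving out cells of clusters with sustentacular markers, and leaving out reference libraries with over 10000 genes. A log2 ratio was taken as the same within 1.5-fold and a share within its interval. A list median was called reversed only where its percentile had been at or below 2.5 or at or above 97.5.

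The procedures were tested on simulated data with 23281 genes and the real numbers of cells, except that OMP cells over reference mature-like neurons used 42 and 138 cells. Genes raised 2-fold had median log2 ratios of 0.93 to 1.07 and the right direction in 89.6% (60 of 67, Neurog1 14 days over uninjured) to 100% of cases, and those raised 4-fold or 8-fold had it in each case. A list of 12 genes raised 2-fold reached percentile 99.9 to 100, and of 200 lists left as they were, 2.5% to 6.5% lay outside percentiles 2.5 to 97.5. Simulated genes varied independently between cells, so these rates do not carry over to real lists whose members rise together in few cells. The clustering placed 120 of 120 simulated cells of 3 classes correctly when cut into 3 clusters. That does not test the cut of the real cells into 12 clusters.

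Genes with many processed pseudogenes, such as Gapdh, Ppia and Tpt1, were listed near 0 while Actb and Malat1 were high, so values of such genes and of the ribosomal list are uncertain. Medians of the odorant receptor list are not interpreted, since each receptor is used by few cells. Analysis used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9, igraph 0.11.9 and leidenalg 0.10.2. Sequence reads were not analysed here, and some single-gene results are not reported here.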

Results

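Single-cell transcriptomes of the mouse olfactory epithelium were profiled with the Fluidigm C1 system, which captures cells 1 by 1 and amplifies the polyadenylated RNA of each. The libraries came from animals 8 weeks old and fell into 6 groups. Of these, 3 groups held cells sorted for the Neurog1-eGFP reporter, which marks neuronal progenitors and their recent progeny: 61 libraries from uninjured epithelium, 51 from 5 days and 26 from 14 days after olfactory bulbectomy. Bulbectomy, the removal of the olfactory bulb, kills the sensory neurons that project to it and sets off their replacement from basal progenitors. Cells sorted for OMP-eGFP, a reporter of mature olfactory sensory neurons, gave 50 libraries 14 days after bulbectomy and 89 from epithelium engrafted by transplantation. The reference came from unsorted, uninjured epithelium, in 2 runs of 96 libraries each.

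After a filter on the number of genes, the comparisons held 46 Neurog1 uninjured cells, 48 at 5 days, 25 at 14 days, 42 OMP cells at 14 days, 29 engrafted cells, and 68 and 70 reference cells from runs 1 and 2. Of the 68, 9 were libraries with more than 10000 genes each, which were kept as labelled although it is not certain that they are single cells. The median depths of the 6 groups were 848317, 1136942, 1099226, 1347935, 501827 and 504103 recovered fragments, and the median numbers of genes were 2864, 2868, 2697, 3356, 2431 and 2406. The engrafted group lost 60 of 89 libraries to the filter, and the median depth of all 89 was 7088 fragments. The labels named no animal, so each group counted as 1 sample, no test was possible and no difference has a replicate check. Intervals are exact 95% binomial intervals over cells. They cover the counting of cells only and leave out variation between animals. As a separate limit on levels, PCR reads without molecular identifiers are not independent molecules. The Neurog1 sorts came from FVB mice, the OMP sorts from B6 mice and the reference from B6;129SF1/J hybrids, so strain cannot be told apart from sort.

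The genes behind the reporters were examined first, since they bear on the labels. Neurog1, the proneural transcription factor of immediate neuronal precursors, was found at a CPM of 10 or more in 50% of the uninjured Neurog1 sort (interval 34.9 to 65.1), 37.5% at 5 days (24 to 52.6) and 48% at 14 days (27.8 to 68.7). With a limit of CPM 50 the first 2 shares were 23.9% and 20.8%. It was found in 0 of 42 OMP cells at 14 days, which allows a share of up to 7.14%, and in 0 of 29 engrafted cells, which allows up to 10.3%. The reference had Neurog1 in 6 cells (4.35%), all 6 among 9 libraries of run 1 with more than 10000 genes each, and in 0 of the other 129. Omp, the olfactory marker protein of mature neurons, was found in 97.6% of OMP cells at 14 days (87.4 to 99.9) and in 75.9% of engrafted cells (56.5 to 89.7). Its share was 58.7% in the uninjured Neurog1 sort (43.2 to 73), 35.4% at 5 days (22.2 to 50.5) and 32% at 14 days (14.9 to 53.5), with mean CPM of Omp at 854, 118.2 and 96.9. Omp was also found in 87% of the reference cells of clusters with sustentacular markers, a supporting cell type that should lack it, at a median depth of 649921 fragments, against 97.8% of the reference mature-like neurons at 410964. The mean CPM in these sets was 1397 and 8068, so presence of Omp alone did not separate cell types in the reference.

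**Figure D1:**
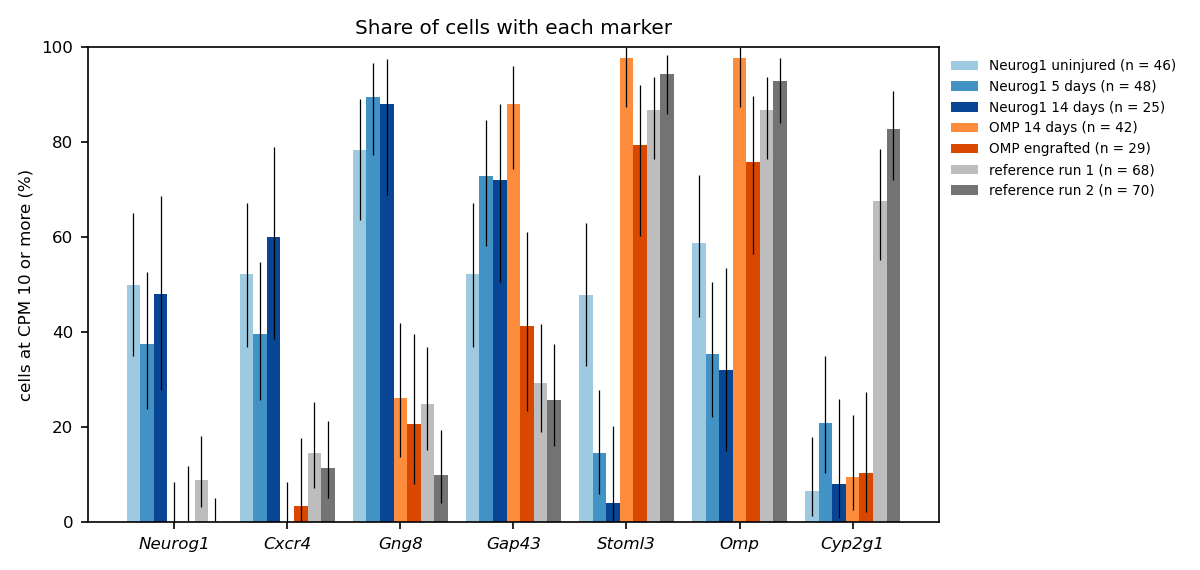
Share of cells (%, vertical axis) with a CPM of 10 or more for Neurog1, Cxcr4, Gng8, Gap43, Stoml3, Omp and Cyp2g1 in the 5 sorted groups and both reference runs, with exact 95% intervals as error bars. Neurog1 was at 50%, 37.5% and 48% in the Neurog1 sorts and at 0 in both OMP sorts, while Stoml3 was at 97.6% in the OMP sort at 14 days.

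The unsorted reference was profiled to hold the cell types of the tissue. Clustering of the cells of all groups together placed 45 reference cells (32.6%, interval 24.9 to 41.1) in 2 clusters like mature olfactory sensory neurons. A further 34 (24.6%, 17.7 to 32.7) fell in 2 clusters like sustentacular cells, the epithelial support cells rich in detoxifying enzymes. Of these, 19 lay in a cluster named on 3 of 10 markers (Ermn, Ugt2a1 and Krt18). The sustentacular markers Cyp2g1 and Sec14l3 were found in all 19. The mature neuron markers Stoml3 and Omp were also found there, in 100% and 94.7% of cells, with Omp at a mean CPM of 2258. Another 4 cells were like immature neurons and 3 like immediate neuronal precursors. The remaining 52 lay in unnamed clusters, of which 2 (35 reference cells) held many sustentacular markers but led with genes such as Rgs5, Lgr5 and Aqp5 that are markers of other types. Run 1 had 41.2% and run 2 24.3% of its cells in the mature-like clusters, and 17.6% and 31.4% in the sustentacular-like ones, and 1 sustentacular-like cluster held cells of run 2 alone. The share in sustentacular-like clusters was 59.4% with Leiden clustering and the mature-like share 48.6% with 8 clusters, so the size of each class depended on the clustering.

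The first comparison asked how sorted progenitors differ from the whole uninjured epithelium. Markers of immature neurons and of neuronal precursors were higher in the uninjured Neurog1 sort, while markers of sustentacular cells were nearly missing from it. All 10 immature neuron markers had a higher mean CPM than the reference, with a median log2 ratio of 1.93 at percentile 100 of matched random lists. Among them were Gng8, a G protein subunit of immature olfactory neurons (78.3% of cells against 17.4%, log2 ratio 3.56), and Gap43, a growth cone protein (mean CPM 466.5 against 109.4). All 7 measured markers of immediate neuronal precursors were higher too (median 1.31, percentile 97.1), with Tex15 at 5946 against 1034 and Neurog1 at 42.2 against 1.87. Of 12 mature neuron markers, 11 were lower (median −1.27, percentile 0.93), among them Adcy3, the adenylyl cyclase of odorant signalling (77.8 against 424.1). The median of all genes was −0.16 in this comparison. The mature median was −1.90 against run 1 alone, −0.49 against run 2 alone and −1.97 without cells of the clusters with sustentacular markers, and the precursor median was 2.23 against run 1 alone.

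Sustentacular markers had a median log2 ratio of −8.26, all 10 lower, and −5.42 without cells of the clusters with sustentacular markers. Sec14l3, a lipid-binding protein, was at a mean CPM of 6.80 against 9088, and the detoxifying enzymes Cyp2g1 and Ugt2a1 were at 10.5 against 4159 and 1.71 against 5409. These 2 enzyme genes were found in 6.52% and 2.17% of Neurog1 cells and in 75.4% and 79% of reference cells. Cyp2g1 was found in 98.6% of reference cells in clusters with sustentacular markers and in 48.9% of the reference mature-like neurons. Stem cell and multipotency genes were lower in 9 of 10 measured members (median −3.63), with the reprogramming factor Klf4 and the Notch effector Hes1 listed at 0 in the Neurog1 sort and at 182.7 and 45.3 in the reference. Notch pathway genes were lower in 5 of 6 (median −3.44). Without cells of the clusters with sustentacular markers the stem cell median was −3.13 (8 members) and the Notch median −3.17 (6 members). Hes1 is a member of both of these lists and of the sustentacular list, so the 3 lists are not independent. All 11 immediate early and dissociation stress genes were lower (median −5.34, and −4.56 without cells of the clusters with sustentacular markers). Of these, Fos, an early response gene, was at 21.2 against 2498, in 13% against 81.9% of cells. The 9 measured immune markers were lower (median −3.56), as were the 3 of fibroblasts (−4.68), the 2 of endothelial cells and pericytes (−5.91), the 5 of Bowman glands (−3.26), 5 of 7 of microvillar cells (−2.17) and 3 of 4 of horizontal basal cells (−3.15). Of the 2 endothelial and pericyte markers, 1 was Rgs5, found in 69.6% of reference cells (mean CPM 4125). Rgs5 was also a leading gene of a cluster with sustentacular markers, so that median does not stand for endothelial cells or pericytes alone. Few libraries carried some of these lists: 2 reference libraries held 73.7% of the immune, 62.7% of the microvillar and 55.4% of the horizontal basal marker CPM. Without the 9 libraries with more than 10000 genes, the microvillar median was −1.17, that of Bowman glands −2.02 (3 members), of horizontal basal cells −2.86 and of immune cells −3.74. The erythroid list rested on Hba-a1, listed at 0 in the sort and at 14.4 in the reference, and was not measured without these libraries.

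Chromatin modifiers were divided between the Neurog1 sort and the reference: 10 of 16 were higher and 6 lower (median 0.70, percentile 92.8), with 7 at least 2-fold higher and 3 at least 2-fold lower. Ezh2, the methyltransferase of Polycomb repressive complex 2, was at a mean CPM of 350 against 21.7 (log2 ratio 3.95), and Suz12, a partner in that complex, at 611 against 115.6. The histone deacetylase Hdac2 was at 466.98 against 62.2, while Hdac1 was lower (3.69 against 34.3). Of 11 genes linked to odorant receptor choice, 9 were higher (median 0.97, percentile 95.1), including the homeodomain factor Lhx2 (888 against 227.2) and Ebf2 (5702 against 1911). Globose basal cell markers were divided, 3 higher and 3 lower (median −0.20), with the chemokine receptor Cxcr4 at 89.6 against 13 and the stem cell marker Lgr5 at 0.02 against 29.8. The genes with the highest ratios also included Fam189a1 (5.53), the Y-linked Eif2s3y (5.46, in 54.3% against 4.35% of cells), the centriole duplication kinase Plk4 (4.77), the centriolar protein Cenpj (4.42) and the transcription factor Bach2 (4.40). G2 and M phase genes were higher in 10 of 13 (median 1.07), but 2 of 46 cells held 94.1% of their summed CPM, and S phase genes were divided (5 higher and 4 lower, median 0.24, with 2 at least 2-fold higher and 2 at least 2-fold lower). At least 1 of 4 Y-linked genes was found in 29 of 46 Neurog1 cells and in 6 reference cells, all 6 among the libraries with more than 10000 genes, so sex-linked genes also differed between these groups.

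The injury comparisons asked how Neurog1-eGFP cells differ after bulbectomy. Mean levels of mature neuron markers were lower at both times than in the uninjured sort, and early neuronal markers went in both directions. All 12 mature markers were lower at 5 days (median log2 ratio −1.41, percentile 0) and all 12 at 14 days (−1.44, percentile 0), beside medians of all genes of −0.13 and −0.17. Stoml3, a stomatin family protein of olfactory neurons, had a mean CPM of 734 uninjured, 68.7 at 5 days and 7.02 at 14 days, and was found in 47.8% (interval 32.9 to 63.1), 14.6% (6.07 to 27.8) and 4.0% (0.101 to 20.4) of cells. The calcium-binding protein S100a5 was at 640, 19.6 and 37.9 (in 19.6%, 6.25% and 20% of cells) and the channel subunit Cnga4 at 150.6, 12.1 and 37.0, while Cnga2, the main subunit of the same channel, was at 518, 283.3 and 510.04. At 5 days the difference lay in the upper part of the distribution, while at 14 days the lower quartile and the median were lower as well. The summed CPM of the 13 mature markers had lower quartiles of 605, 870 and 508 per cell. The medians were 1607, 1866 and 1151, and the upper quartiles 6384, 2938 and 3154. The mixture of cells differed too. In the unnamed cluster that held 25 of 42 OMP cells at 14 days lay 8 of 46, 2 of 48 and 1 of 25 Neurog1 cells. The mature-like clusters held 2, 0 and 0 of them. Between 14 and 5 days the mature list did not differ in a common direction (median −0.00, 6 higher and 6 lower). Both injured groups had a larger median depth than the uninjured one. Xist was found in 19.6% of uninjured cells, 4.17% at 5 days and 0 of 25 at 14 days, with overlapping intervals. Y-linked genes were found without Xist in 25 of 46, 42 of 48 and 19 of 25 cells. Both kinds were found together in 4, 2 and 0 cells. The share of cells with a Y-linked gene was thus higher in both injured groups than in the uninjured one. The labels give no sex, and an effect of the sex of the animals was not tested.

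**Figure D2:**
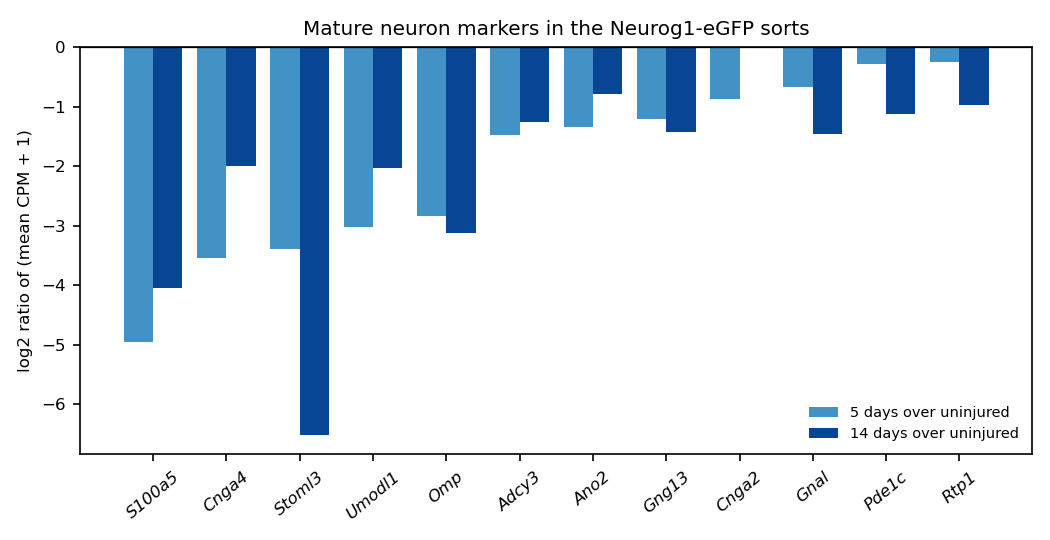
Log2 ratio of mean CPM + 1 (bars) for 12 mature neuron markers in the Neurog1-eGFP sorts at 5 days and 14 days after bulbectomy over the uninjured sort. Every bar lies below 0, from −0.02 for Cnga2 at 14 days to −6.52 for Stoml3 at 14 days, and none has a replicate check.

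Gap43 was at a mean CPM of 466.5 uninjured, 988 at 5 days and 850 at 14 days, and in 52.2%, 72.9% and 72% of cells, with overlapping intervals. The microtubule protein Dcx was at 954, 1686 and 1204, whereas Gng8 was at 115.3, 82.7 and 53.3. The immature neuron list as a whole was near 0 at 5 days (median −0.04, 4 of 10 higher) and at 0.32 at 14 days (7 of 10 higher), and the precursor list was at 0.16 and 0.35. Of the globose basal cell markers, 4 of 5 were lower at 5 days (median −0.36) and 4 of 5 higher at 14 days (0.52), and all 5 were higher at 14 than at 5 days (0.98, percentile 91.7), with Ezh2 at 350, 255.01 and 504. Chromatin modifiers had medians of −0.15 and 0.38. Within that list Suz12 was at 611, 244.6 and 138.4 and Hdac2 at 466.98, 587 and 1033. Genes of odorant receptor choice were lower in 8 of 11 at 5 days (−0.26) and in 10 of 11 at 14 days (−0.35). The unfolded protein response genes, which act during receptor choice as well as in stress, had medians of 0.35 and 0.41, with Herpud1 at 180, 374.7 and 353.8.

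Outside the fixed lists, Tmem87b was higher at both times than in the uninjured sort (371.4 at 5 days and 155.7 at 14 days against 10.2), as was Ssr1, a subunit of the translocon-associated complex (966 and 1025 against 385.3). Bcl11a, a transcription factor of neuronal development, was at 323.9 at 5 days against 85.2. Lyst was at 86.2 and Paxbp1 at 782 at 14 days, against 6.99 and 315.4. Tmem117 and Slc24a5 were lower at both times: 28.9 and 7.64 against 175.9, and 231.2 and 383.6 against 815. Gpr171 was at 8.25 at 5 days, 68.5 at 14 days and 245.6 uninjured, and Limk2, a kinase of actin turnover, at 7.83 at 5 days against 92.8. At 14 days the presynaptic protein Pclo was at 673 against 1528. Between the injured groups, the centriole assembly gene Sass6 was at 78.4 at 14 days against 3.30 at 5 days, and the glutamine synthetase gene Glul was at 9.86 against 50.4.

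G2 and M phase genes were lower at 5 days than uninjured in 11 of 13 (median −3.02), and 12 of 14 were higher at 14 days (0.65). Against 5 days, 13 of 14 were higher at 14 days (median 3.78, percentile 100). Few cells carried these values: Top2a, the topoisomerase of dividing cells, was found in 1 of 46 cells uninjured, 1 of 48 at 5 days and 3 of 25 at 14 days, and 2 cells held 94.1%, 81% and 72.7% of the summed CPM in the respective groups. The last median was 6.03 with a pseudocount of 0.1 and 1.44 with 10. S phase genes were divided, with 3 higher and 5 lower at both times against uninjured (median −0.89 at both), while their summed mean CPM was 195.8 uninjured, 343.2 at 5 days and 323.04 at 14 days, so no direction was read for them.

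Sustentacular markers were higher at 5 days than uninjured in all 8 measured members (median 5.03), with Cyp2g1 at a mean CPM of 470 against 10.5. Here 2 of 48 libraries (4.17%, interval 0.509 to 14.3) held 94.7% of the group's summed marker CPM. Both had 8 or 9 sustentacular markers and no Neurog1, Gap43, Gng8 or Omp. No library of the uninjured or the 14 day sort reached these levels. At lower levels, the 4 measured sustentacular markers were also higher at 14 days than uninjured (median 2.79, percentile 99.6, and 3.10 without cells of clusters with sustentacular markers). The median summed marker CPM per cell was 0 uninjured, 19.7 at 5 days and 16.7 at 14 days. Immediate early genes (8 of 9 higher, median 3.31) and Notch pathway genes (4 of 5 higher, median 2.52) were higher at 5 days together with the sustentacular markers. Without the cells of clusters that hold sustentacular markers, the 3 medians were 1.73, 0.18 and −2.76. They then rested on 6, 5 and 3 members, since the limit on low values was applied again, so the medians compare unlike sets of genes. The medians for 14 over 5 days changed as well. The sustentacular median of −4.06 was 0.58 without these cells (6 members). The immediate early median of −1.68 was −0.10 (6 members) and the Notch median of −1.75 was 2.98 (4 members).

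**Figure D3:**
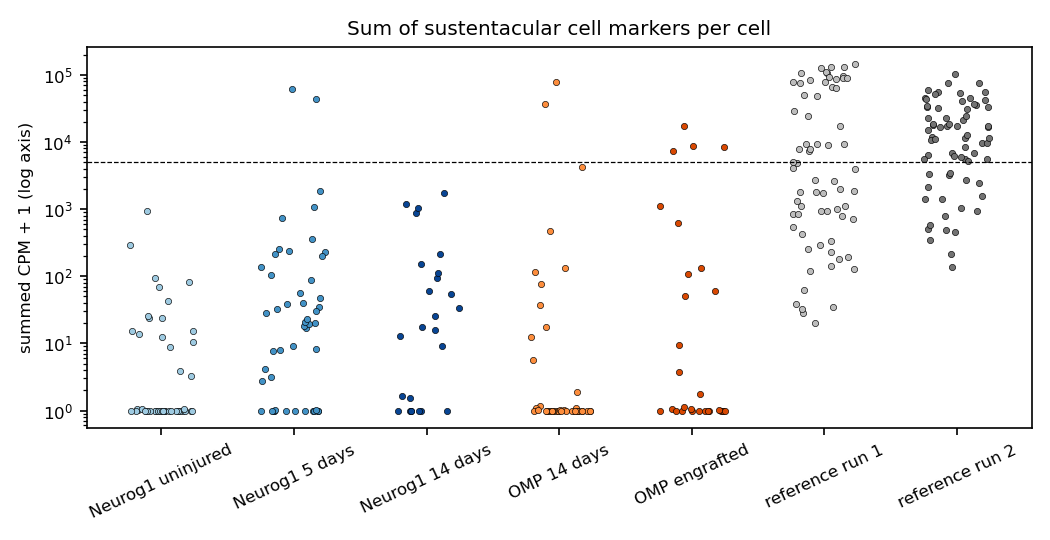
Summed CPM + 1 of 10 sustentacular markers per cell (log axis, 1 point per cell) in each group, with a dashed line at 5000. The 2 highest points of the Neurog1 sort at 5 days lie at 61434 and 43636, and 76 reference cells (55.1%) lie above the line with 6 or more markers.

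At 14 days after bulbectomy the 2 reporters were compared with each other. The OMP sort had higher levels of every measured mature marker and lower levels of every precursor, globose basal cell and mitotic gene measured. The 12 mature markers had a median log2 ratio of 3.29 (percentile 100), with Stoml3 at a mean CPM of 2748 against 7.02, the calcium-activated chloride channel Ano2 at 789 against 17.4 and Gng13, a G protein subunit of odorant signalling, at 751 against 75.9. All 7 precursor markers were lower (median −5.29, percentile 0): the proneural factor Neurod1 was at 1.24 against 309.2 and Tex15 at 143.8 against 5675. The 5 globose basal cell markers were lower (−4.13), with Cxcr4 listed at 0 in all 42 OMP cells and found in 60% of the Neurog1 cells, and so were all 13 measured G2 and M phase genes (−4.22). Immature neuron markers were lower in 8 of 10 (median −1.33), although Stmn1, a regulator of microtubules, was at 1641 against 278.5 and Dcx at 1829 against 1204. The median of all genes was 0.04.

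Genes of transmitter release were higher in the OMP sort in 9 of 11 (median 1.03, percentile 93.1), including the synaptic vesicle sensor Syt1 (335.8 against 53.2), Snap25 (2298 against 645) and the glutamate transporter Slc17a6 (536 against 261.8). Axon growth and guidance genes were divided (7 higher, 6 lower, median 0.14). The adhesion molecule Kirrel2 (207.5 against 24.3) and the receptor Plxna3 (170 against 16.9) were higher, Epha5 was at 40.7 where the Neurog1 sort was listed at 0, and the guidance receptor Robo2 (103.9 against 313.5) was lower. Cilia genes were higher in 10 of 12 (0.34). Chromatin modifiers were lower in 12 of 17 (median −1.04, percentile 2.25), with Ezh2 at 63.2 against 504 and Hdac2 at 112.02 against 1033, while Hdac1 was at 48.3 against 2.88. The potassium channels Kcnj2 (203.9 against 0.06) and Kcnma1 (116.97 against 0.05) and the mitochondrial anchor Snph (174.9 against 0.07) were among the genes with the highest ratios. Among the lowest were the retinoid-binding protein Crabp1 (1.75 against 330.7) and the neuronal factor Nhlh2 (2.07 against 320), and St18 and Gad2 were listed at 0 against 120.6 and 106.9. Sustentacular markers were higher (median 4.50), with 95.7% of their summed CPM in 2 of 42 libraries, and the median was −0.91 without the cells of clusters that hold them. The groups also differed in Xist, the noncoding RNA of X inactivation (78.6% of OMP cells and 0 of 25 Neurog1 cells), and in the Y-linked genes Ddx3y and Eif2s3y, listed at 0 in the OMP sort and found in 44% and 48% of Neurog1 cells.

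OMP-eGFP cells 14 days after bulbectomy were also set against the 45 reference mature-like neurons, that is, neurons of uninjured tissue. The reference cells were chosen by cluster, which leaves out cells of clusters like immature neurons, whereas the OMP cells were not chosen in this way. Differences in immature markers are therefore given as values only. Of these markers, 8 of 10 were higher in the cells after bulbectomy (median 2.47, percentile 99.8, beside 0.27 for all genes, and 1.40 with the strict cell filter, 1.65 with no cell filter and 1.87 with a pseudocount of 10), with Gap43 at a mean CPM of 695 against 37.8 and in 88.1% against 20% of cells. Stmn1 was at 1641 against 85.5 and the precursor factor Sox11 at 4424 against 811. The precursor list had a median of 1.19. It was 4.78 against run 1 alone (3 members) and −0.33 against run 2 alone (4 members), so no direction was read for it. The intermediate filament gene Vim was at 92.7 against 1.11 (log2 ratio 5.47), Ncam2, an adhesion molecule of olfactory axons, at 201.1 against 10.1, and Camk2n1, an inhibitor of a calcium-dependent kinase, at 129 where it was listed at 0 in the reference. Immediate early genes were lower in 10 of 11 (median −0.90, percentile 4.18), with Fos at 39.2 against 1584, in 21.4% against 62.2% of cells. That median was −3.01 without cells of clusters with sustentacular markers, −0.03 with no filter on cells and −1.71 against run 2 alone.

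In the same comparison the 5 Notch pathway genes were lower (median −3.94) and 4 of 5 stem cell genes (−2.32). The stem cell median depended on the cell filter: it was 0.62 with no filter and 0.22 with the strict filter. Chromatin modifiers were higher in 9 of 16 (median 0.64), with Ezh2 at 63.2 against 0.12. Sustentacular markers were lower in 7 of 10 (−0.79, and −4.91 without cells of clusters with sustentacular markers, which leaves out 2 OMP cells with 95.7% of the group's summed marker CPM), and Sult1c1 was listed at 0 against 1285. Sustentacular RNA was widespread among the reference neurons: Sec14l3 was found in 84.4% of them and in 11.9% of the OMP sort. The immune markers were lower in all 4 measured (−4.76), but 2 reference cells held 99.9% of their CPM. Ensheathing glia markers rested on Apoe alone (0.43 against 460.7, in 11.1% of reference neurons) and 98.2% of the latter came from 2 cells. Mature markers are not given here as differences, since they define the reference clusters. The OMP cells were deeper (1347935 against 410964 fragments), and 39 of 42 lay in unnamed clusters.

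Engrafted OMP-eGFP cells were compared with OMP-eGFP cells 14 days after bulbectomy, both from B6 mice. Mature neuron markers were at similar mean levels in both, and mean levels of immature markers were lower in the engrafted cells. The groups lay in different clusters: 15 of 29 engrafted cells were in mature-like clusters, 4 in the immature-like one and 10 in unnamed ones, against 3, 0 and 39 of 42 cells at 14 days, so the means stand for unlike mixtures of cells. The mature list had a median log2 ratio of −0.13 (3 of 12 higher), less negative than the −0.34 of all genes. The summed CPM of the 13 mature markers had means of 16682 and 17172 and medians of 17504 and 16588, but lower quartiles of 1012 in engrafted cells and 10372 at 14 days. Omp itself was at a mean CPM of 2711 against 1314, and Ano2 at 122.1 against 789. Immature markers were lower in 8 of 10 (median −1.08, percentile 2.24): Gap43 was at 272.1 against 695 (41.4% against 88.1% of cells), Stmn1 at 294.4 against 1641 and Dcx at 700 against 1829. Transmitter release genes were lower in 9 of 10 (median −0.98, percentile 6.59), with Syt1 at 106.7 against 335.8, and cilia genes in 10 of 12 (−0.59). Camk2n1 was at 3.31 against 129, the formin Daam1 at 0.13 against 63.9 and the dynactin subunit Dctn2 at 13.4 against 167.99. Sox11, Marcks and Dync1i2 had higher mean levels in engrafted cells (7294 against 4424, 2705 against 2466 and 393.4 against 200) but were found in fewer of them, so no order was read for these. The engrafted libraries held fewer fragments (501827 against 1347935).

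Markers of some other cell types were also present among the engrafted cells. The sustentacular list was not higher than in OMP cells at 14 days (median −0.47, and −1.29 without cells of clusters with sustentacular markers). Rgs5, a pericyte marker that the reference clusters with sustentacular markers also express, was at a mean CPM of 20856 in engrafted cells (3 of 29, with 73.2% of the sum in 2 cells) against 0.07. Bowman gland markers were higher in all 4 measured members (median 4.80, 95.3% in 2 cells), microvillar markers in all 4 (3.54, 99.6% in 2 cells), Notch genes in all 5 (2.17) and stem cell genes in 5 of 6 (2.15, and 0.23 without cells of clusters with sustentacular markers). With the strict cell filter the Bowman gland median was −1.28 (2 members) and the microvillar median −4.03 (1 member), and the latter was −4.50 without cells of clusters with sustentacular markers. Libraries with 6 or more sustentacular markers and a summed CPM of 5000 or more numbered 3 of 29 engrafted and 2 of 42 OMP cells at 14 days. Xist was found in 0 of 29 engrafted cells, which allows up to 10.3%, against 78.6% at 14 days, and Eif2s3y in 41.4% of engrafted cells against 0 of 42.

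**Figure D4:**
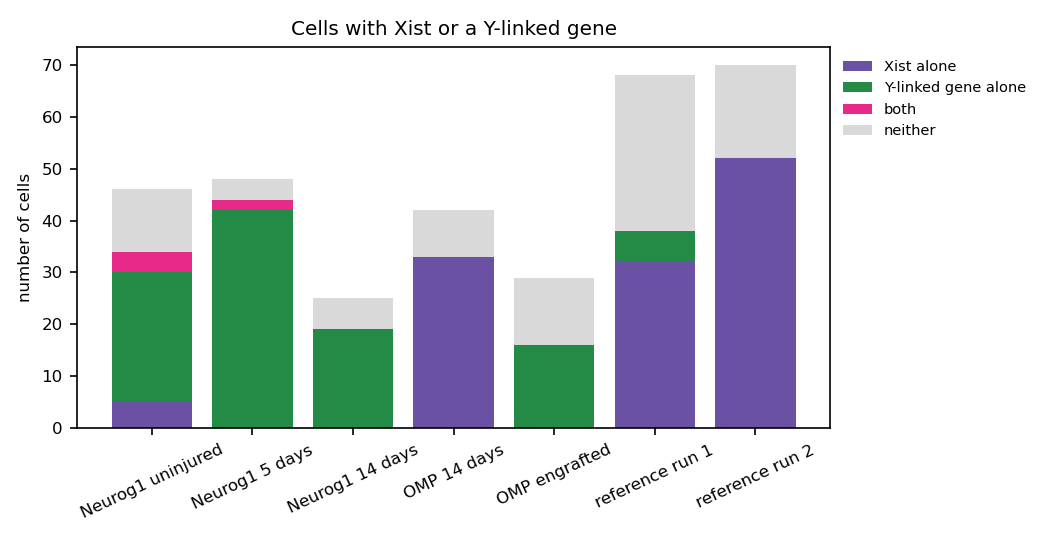
Number of cells (stacked bars) with Xist alone, with at least 1 of 4 Y-linked genes alone, with both or with neither, per group, each gene counted at a CPM of 10 or more. The OMP sort at 14 days has 33 of 42 cells with Xist and 0 with a Y-linked gene, and the engrafted sort 0 and 16 of 29.

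Odorant receptor genes were counted per cell, since a mature neuron typically uses a single receptor. The median number of receptor genes at a CPM of 50 or more was 1.5 in the uninjured Neurog1 sort, 1 at 5 and at 14 days, 2 in OMP cells at 14 days, 1 in engrafted cells and 2 in the reference mature-like neurons. Exactly 1 receptor was counted in 31% of OMP cells at 14 days (interval 17.6 to 47.1), 48.3% of engrafted cells (29.4 to 67.5) and 35.6% of the reference mature-like neurons (21.9 to 51.2). The shares in the Neurog1 groups were 32.6%, 27.1% and 32%, so this measure did not set OMP cells at 14 days apart from them. No receptor was counted in 17.4%, 25.0% and 24% of the Neurog1 groups, in 2.38% of OMP cells at 14 days and in 13.8% of engrafted cells. The top receptor held 90% or more of a cell's receptor CPM in 45.7%, 54.2% and 60% of the Neurog1 groups, 69% of OMP cells at 14 days and 75.9% of engrafted cells. Median receptor CPM per cell was 912, 696 and 3291 in the Neurog1 groups, 6717 and 7530 in the OMP groups and 8642 in the reference mature-like neurons. The 42 OMP cells at 14 days had 37 different top receptors, and Olfr180 was the top receptor in 3 of them. In reference cells of clusters with sustentacular markers, a cell type that should use no receptor, the median number was 3, and the cause was not tested. With a limit of CPM 200, exactly 1 receptor was counted in 57.1% of OMP cells at 14 days and 65.5% of engrafted cells. At 10 in the FPKM table the shares were 23.8% and 27.6%.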

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

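Among the tests in this part, all but the thinning test of Xist were chosen after the result was seen. Libraries below the gene filter, which no comparison used, were searched for the reporter genes. Neurog1 was found in 26.3% of those from the Neurog1 sorts (5 of 19, interval 9.15 to 51.2), against 0 of 54 reference libraries below the filter, which allows up to 5.56%. This signal in unused data, above the level in the reference, is why the result is listed here. Omp was found in 26.5% of such libraries of the OMP sorts (18 of 68, 16.5 to 38.6). In those of the reference it was found in 66.7% (36 of 54, 52.5 to 78.9), so its share was not above the reference. Most of these OMP libraries were engrafted. Before the filter, the median depth was 7088 fragments in the engrafted group and 412719 in the reference. The Omp shares therefore come from libraries of unlike depth, and no conclusion is drawn from their order. No explanation was tested for the Neurog1 or the Omp result.

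The first pattern weighed was the high level of sustentacular markers in the Neurog1 sort at 5 days. Free RNA spread over the cells is argued against for the 2 richest libraries alone, which held 94.7% of the summed marker CPM of 48 libraries. For the low level in the other 46 it stays open, as 56.5% of them (interval 41.1 to 71.1) had 1 or more sustentacular markers, against 28.3% of uninjured cells (16 to 43.5). Whole cells of another type passing the eGFP gate remain a possible explanation for the 2 libraries: 5 libraries of 71 in the OMP-eGFP sorts, a different reporter, reached the same marker limits, although only 2 of these 5, both engrafted, lacked Neurog1, Gap43, Gng8 and Omp. Injury at 5 days cannot be told apart from this, since such libraries made up 4.17% at 5 days (interval 0.509 to 14.3) and 0 of 46 uninjured cells, too few to separate the shares. Both OMP sorts came from epithelium after bulbectomy or transplantation, so their 5 libraries cannot separate the 2 explanations either.

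The second pattern was the split of groups by Xist and Y-linked genes. Low depth of the engrafted libraries is argued against as the reason for their lack of Xist, because OMP cells at 14 days kept Xist in 81% (34 of 42, interval 65.9 to 91.4) after thinning to 100000 fragments. Animals of one sex per OMP group remain a candidate explanation: of 49 OMP cells with Xist or a Y-linked gene, 0 had both, and each OMP group had only 1 of the 2 kinds. The Neurog1 uninjured sort had 5 cells with Xist alone, 25 with Y-linked genes alone and 4 with both, so it was not split in this way. The Neurog1 sort had 0, 42 and 2 such cells at 5 days and 0, 19 and 0 at 14 days, so the injury comparisons also differ in these genes. The labels give no sex, and any effect of sex on other genes was not tested.

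The third pattern was a group of 9 reference libraries with consecutive numbers in run 1, at 12256 to 16307 genes where the next highest library had 6157. Greater depth is argued against, since the ratio of their median fragments to that of the other run 1 libraries was 0.838. Several cells in one library remain a possible explanation, as the median number of cell types with 3 or more markers among the 2165 highest genes of each library was 2 times that of the others (4 against 2), at the limit set and with overlapping ranges (3 to 7 against 1 to 4). RNA of one source in several wells, such as bulk control material, is left open: in sets of 3 in order of number, 9 of 9 libraries had both nearest libraries in their own set over the 500 genes of highest mean (correlations of 0.955 to 0.990 within sets and up to 0.915 between them), but 1 of 9 over all genes. Cells of other animals are open as well, with Y-linked genes in 6 of the 9 libraries and in 0 of the other 129 reference libraries.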

How the results depend on the processing

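The settings that left out cells of clusters with sustentacular markers or reference libraries with over 10000 genes, thinned the fragments or set a limit of 50000 fragments were chosen after the data were seen, and the others before. No paired analysis was possible because the labels name no animals, and no test was run. Of 4671 values under alternatives, 3792 stayed the same, 853 moved and 26 reversed. Some could not change. The settings on low values act on list members alone, so ratios of single genes were fixed under them. The limit of 50000 fragments left out cells only in engrafted over 14 day OMP cells. Leaving out reference libraries with over 10000 genes removed no cell from OMP cells over reference neurons. The count of values that stayed the same is therefore not a measure of stability. Among the main values, which were chosen lists and shares, 35 moved, 0 reversed and the others stayed the same. The 0 is partly set by the labels, since shares and list medians within the percentile limits could not be called reversed. The mature median ranged from −0.63 to 0.15 for engrafted over 14 day OMP cells and from −0.50 to 0.07 for 14 over 5 days. The immature median at 5 days over uninjured ranged from −0.04 to 0.10. Some medians given in the results are among the 26 that reversed. Mature markers stayed lower than uninjured under every alternative run, with medians of −1.48 to −1.18 at 5 days and −1.58 to −1.29 at 14 days. Immature markers in engrafted over 14 day OMP cells ranged from −1.37 to −0.61. Unless a reason is given, the cause was not tested. For values of opposite direction, the value under the chosen settings follows in brackets where the report does not give it.

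With detection at CPM 50, Neurog1 was found in 23.9% of uninjured and 20.8% of 5 day cells, and at 1 in the FPKM table Stoml3 was found in 33.3% of 5 day cells. Exactly 1 receptor was counted in 57.1% of OMP cells at 14 days with receptors at CPM 200, and in 27.6% of engrafted cells at 10 in the FPKM table. The share of reference cells like mature neurons was 41.2% in run 1 alone, 24.3% in run 2 alone, 48.6% with 8 Ward clusters, 24.5% with no cell filter and 18.7% with the strict filter. That of sustentacular-like cells was 17.6% in run 1 alone, 59.4% with Leiden, 41.3% with 1000 variable genes, 36.5% with no cell filter and 41.8% with the strict filter.

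A pseudocount of 0.1 gave −9.59 for sustentacular markers (Neurog1 uninjured over reference) and 6.03 for G2 and M phase genes (14 over 5 days), and a pseudocount of 10 gave −6.26 and 1.44. With 10, precursor markers in OMP over Neurog1 cells were at −3.17 and immature markers in OMP cells over reference neurons at 1.87. With no filter on low values, which adds members near 0, the precursor median was −3.89. In the same setting, stem cell genes in OMP over Neurog1 cells were at 0.053 (−3.12). Endothelial and pericyte genes in OMP cells over reference neurons were then at 0.018 (−9.86, 1 member, Rgs5). With members at CPM 50, which left 3, G2 and M phase genes were at 5.78 for 14 over 5 days.

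With no cell filter, which adds shallow libraries, Omp and Gap43 were found in 40.4% and 20.2% of engrafted libraries. Ppp1r15b at 14 days over uninjured was at −0.67 (0.77), and in engrafted over 14 day OMP cells Dync1i2 was at −0.42 (0.97), Wdr17 at −0.19 (0.85), Marcks at −0.64 (0.13) and Edc4 at 0.79 (−4.11). In OMP cells over reference neurons, horizontal basal cell markers were at 0.51 (−3.50), immature markers at 1.65, stem cell genes at 0.62, immediate early genes at −0.025, Matn2 at −0.62 (5.42) and Ugt2a1 at 1.27 (−1.88).

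With the strict filter, Omp was found in 100% of OMP cells at 14 days, and precursor markers in OMP over Neurog1 cells were at −6.45. Microvillar markers, with 1 member left, were at 0.86 at 5 days (−6.00, 3 members) and 1.52 at 14 days (−3.46, 4 members) over uninjured and at −4.03 in engrafted over 14 day OMP cells, where Bowman gland markers, with 2 members left, were at −1.28. Over reference neurons, of which 17 were left, immature markers were at 1.40, G2 and M phase genes at 1.07 (−3.86), stem cell genes at 0.22, immediate early genes at −1.95 and Cd99l2 at −0.67 (5.83). With run 2 alone, also with 17 reference neurons, G2 and M phase genes (1 member) were at 0.67, immediate early genes at −1.71 and ribosomal genes at 0.95 (−0.50).

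Without cells of clusters with sustentacular markers, sustentacular medians were −5.42 for Neurog1 uninjured over reference, 0.58 for 14 over 5 days and −0.91 for OMP over Neurog1 cells, where precursors were at −6.12. By construction this removes the libraries rich in these markers. Microvillar markers, with 1 or 2 members left, were at 0.92 at 5 days (−6.00) and 3.06 at 14 days (−3.46) over uninjured and at −4.50 in engrafted over 14 day OMP cells. Notch genes at 5 days over uninjured, with 3 members left, were at −2.76. Immediate early genes in OMP cells over reference neurons were at −3.01, where the setting removed 2 OMP cells and no reference neuron.

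Thinning to 100000 fragments left out 1 Neurog1 uninjured, 3 engrafted and 2 reference cells, and the main shares of reporters and markers stayed within their intervals. Depth limits shares of genes near CPM 10 in the shallowest libraries, the lowest of which held 13369 fragments.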

Other observations

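No explanation is tested in this part, and the values below were chosen after the data were seen. Several gene lists not described above are given here for the uninjured Neurog1 sort over the reference. Cilia genes had a median log2 ratio of −0.27 (5 of 11 higher, 4 at least 2-fold higher and 3 at least 2-fold lower), apoptosis and p53 genes −0.31 (4 of 9 higher) and axon growth and guidance genes 0.65 (8 of 14 higher, 6 at least 2-fold higher and 6 at least 2-fold lower), with the olfactory adhesion molecule Ncam2 at a mean CPM of 318.6 against 37.3 and the guidance receptor Robo2 at 604 against 170.4. Unfolded protein response genes were lower in 7 of 9 (−0.62) and transmitter release genes in 8 of 11 (−1.07), including Syt1 at 143.2 against 302.2, and the latter median was −0.46 without the reference libraries with over 10000 genes. Interferon and inflammation genes were lower in all 7 measured (−2.51), respiratory ciliated cell markers in all 3 (−1.31) and ensheathing glia markers in 2 of 3 (−1.08). Ribosomal protein genes were divided (30 of 55 higher, median 0.21), with medians of −0.44 against run 1 alone and 1.2 against run 2 alone. The odorant receptor list had a median of −3.38 and is not interpreted.

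In the Neurog1 sort after bulbectomy, cilia genes had medians of −0.06 at 5 days and −0.33 at 14 days, with 1 and 0 of 11 at least 2-fold apart from the uninjured level. Apoptosis and p53 genes went in both directions (−0.15 and 0.12), with 2 of 9 at least 2-fold higher and 2 at least 2-fold lower at each time. Transmitter release genes had medians of −0.58 and −0.43, with Slc17a6 at 332.5 uninjured, 58.1 at 5 days and 261.8 at 14 days and Syt1 at 143.2, 46.7 and 53.2. Kirrel2, an adhesion molecule that sorts axons, was at 54.6, 0.22 and 24.3, found in 15.2% of cells uninjured, in 0 of 48 at 5 days and in 1 of 25 at 14 days.

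Clusters grouped the sorted cells as follows, given as counts only. Of the Neurog1 cells, 20 of 46 uninjured, 15 of 48 at 5 days and 9 of 25 at 14 days lay in the cluster like neuronal precursors, and 8, 22 and 11 in the cluster like immature neurons. Of the engrafted cells, 15 of 29 lay in clusters like mature neurons and 4 in that like immature neurons, where 0 of 42 OMP cells at 14 days lay. A cluster of 9 cells led by the mitotic genes Kif11, Ccnb1, Nusap1 and Tpx2 stayed unnamed and held 1, 2 and 2 Neurog1 cells and 4 reference cells. Olfr672 was the top receptor in 6 reference cells. Among the other libraries, 3 pairs with numbers 1 or 2 apart were nearly alike over all genes: 2 pairs of the Neurog1 sort at 5 days (correlations of 0.994 and 0.960) and 1 of the reference (0.943), where the median correlation of a cell with its nearest was 0.477. They were counted as separate cells, and no alternative left out a library of a pair. Shares and intervals at 5 days therefore treat the libraries of these pairs as independent, which was not tested.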
